A study of Mus musculus with 11 samples.

How the data were processed

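The libraries were small RNA libraries of mouse embryonic stem cells, a cell type derived from the early embryo. Per the labels' protocols the cells were grown without feeder cells in medium with the 2i inhibitors and LIF, total RNA was extracted with peqGold TriFast, and libraries were made with the NEBNext Multiplex Small RNA kit. Groups and clone numbers were taken from the sample titles. The 3 KO titles name the same clone, 261, and nothing in the labels says that they came from separate cultures.

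The authors deposited a table of read counts for 1966 mature miRNAs in 11 libraries, not normalized per the file headers, and a table of the same miRNAs in a scaled unit of RPM that the file header calls pRPM. The submitters' processing notes name STAR, bedtools and the genome build GRCm38.p6, without versions or roles; the counting rule, the treatment of strand and the adapter trimming are not given in the sources used here. A deposited file labelled as piRNA counts was byte for byte identical to the file of pRPM values, so it was not used here and no piRNA result is reported. The fixed plan had taken library sizes from the piRNA counts; TMM scaling within the miRNA counts, which had been fixed as an alternative, took that place. The pRPM values were whole multiples of what 1 read was worth: 100% of them gave a whole number of reads within 0.01 reads, and 100% equalled the counts. Libraries of the same group shared 1 pRPM total, from 85006 in KO, 138451 in untreated E518K, 683476 in induced E518K and 685878 in untreated wild type to 938495 in induced wild type, so that the authors' scaling set the level of each group by a constant whose origin is not given in the sources used here.

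Of the counts from 1 to 40, 90.3% were even, from 86.6% to 93.6% per library, so most small RNAs seem to have been counted 2 times each. A floor of 3 small RNAs was therefore set at 6 counts per library for every miRNA with 0 counts, and folds against such groups were given as lower bounds. In 36 sets holding 77 miRNAs the counts were the same within 2% over the libraries, as for miR-292a-5p and miR-292b-3p, and 24 of 44 such pairs came from hairpins on opposite strands of the same place. The repeated part of their counts, each set without its largest member, was from 0.228% to 27.0% of the counts of a library. These miRNAs held more than that, and the values of all 77 are uncertain. The hairpin position of 1964 of 1966 miRNAs (99.9%) was taken by name from RefSeq gene records, and 69 miRNAs had several hairpins. Strands and overlapping genes were taken from the GENCODE annotation of GRCm38.p6.

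Tests were run with edgeR 4.0.16 (robust quasi-likelihood fit over all 11 libraries in 5 groups, TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15) in R 4.3.3, with Benjamini-Hochberg adjustment over the 730 miRNAs tested and a threshold of 0.05. Unless another tool is named, adjusted p-values of single miRNAs are from edgeR. The groups without doxycycline had 1 library each, which was assumed to vary like the other groups. All libraries shared 1 estimate of the spread. P-values for the KO use this shared estimate, which draws on the wild-type and E518K clones too. The spread between the 3 KO samples may be technical, and the spread between KO clones was not measured. The replicates of each group differed by more than counting noise (chi-square per degree of freedom from 24.3 to 557, Pearson's r of log2 counts from 0.955 to 0.982), so no pair was taken for 1 library listed 2 times. This does not show that the KO libraries came from separate cultures.

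Lists of miRNAs were fixed by name, and 16 of 18 had at least 3 tested members. They were compared with the other tested miRNAs by camera (limma 3.58.1, on voom values, preset correlation 0.01), with Benjamini-Hochberg adjustment over the 16 lists; camera with an estimated correlation, and fry, which asks whether a list's members move 1 way on balance without comparing them with other miRNAs, were alternatives. The median per library of the log2 ratio to the wild-type mean was taken on CPM plus a pseudocount of 1, and its groups were compared by a two-sided exact permutation test. Levels are TMM-scaled CPM. Binomial intervals are exact (Clopper-Pearson, 95%) and were taken on counts divided by 2, since most small RNAs seem to be counted 2 times. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Overlaps of calls that share the wild-type libraries were set beside 50 simulations of unchanged groups.

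Groups, tests, lists, alternatives and the rule for naming miRNAs were fixed before the data were examined. In each comparison of induced groups the rule named the 8 most abundant miRNAs of induced wild type, the 8 largest fitted folds in each direction among those that passed the test, did not overlap between groups and reached 10 CPM in the higher group, every tested DGCR8-independent miRNA and Dgcr8 hairpin, and the 2 most abundant members of each other list; for the untreated libraries it named the first set and the 5 largest fitted folds in each direction, which place miRNAs with 0 counts in a group first. Members of the last set were given only as counts where camera made no call for their list. Alternatives fixed with them were total counts, DESeq2 size factors (DESeq2 1.42.0), scaling by the summed counts of the DGCR8-independent list, no filter, the Wald test of DESeq2, a fit of only the 2 groups compared, and leaving out each replicate. Others were chosen after seeing the data: edgeR on the reads recovered from the pRPM values with the authors' constants as library sizes, the pRPM totals read as shares of a pool of reads with the odds of that share as scaling, merging miRNAs that count the same reads, in the tests and in the shares of the counts, and counts divided by 2. The edgeR test on the recovered reads called 433 miRNAs between E518K and wild type, 635 between KO and wild type and 441 between E518K and KO.

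The steps were tested on simulated data made from the wild-type means and the real library sizes, with 200 changed miRNAs before filtering. All groups used these means, with about as many rises as falls. The general shift of the KO and its miRNAs without counts were therefore not simulated, and the rates below need not hold for the real comparisons. With the library sizes of E518K and wild type (566 miRNAs tested), 35.1% of those changed 2-fold, 86.7% of those changed 4-fold and 93.0% of those changed 8-fold were called. Of the calls, 1.57% were on unchanged miRNAs. For KO against wild type (512 tested) these were 36.2%, 83.0%, 90.6% and 7.14%, and for E518K against KO (598 tested) 25.5%, 77.8%, 91.7% and 2.65%. Other tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and RNAfold 2.7.2. The counts carry no external reference such as spike-ins here, so that no scaling within them measures the amount of miRNA per cell.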

Results

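Small RNA libraries from mouse embryonic stem cells were compared across 3 genotypes of DGCR8, the RNA-binding partner of the nuclease Drosha in the microprocessor, which releases miRNA hairpins from their primary transcripts. Cells without DGCR8 (KO) were compared with cells carrying a doxycycline-inducible vector for wild-type DGCR8 or for DGCR8 E518K, a change of a glutamate in the protein that recurs in Wilms tumours. The series held 11 libraries in 5 groups. These were 3 induced KO libraries, 3 induced wild-type libraries (clones 10, 12 and 16), 3 induced E518K libraries (clones 8, 13 and 15), and 1 library each of wild-type clone 10 and E518K clone 8 without doxycycline. Induction was 300 ng/mL for 48 h. All 3 KO libraries carried the label of the same clone, 261. The spread between these samples may be technical, and the spread between KO clones was not measured. P-values for the KO use 1 estimate of the spread shared by all groups. Of 1966 mature miRNAs listed, 1347 had a count in any library and 730 passed the low-count filter. Total miRNA counts ran from 166676 to 208846 in the KO, from 1050564 to 1797240 in induced E518K and from 3394216 to 6128734 in induced wild type. They were 1421247 in untreated wild type and 264507 in untreated E518K. The KO libraries therefore had the fewest miRNA counts, and a count of 0 there allowed up to 12.8 to 18.3 scaled CPM, against 1.11 to 2.94 in induced wild type. The sequencing depth of the libraries is not known from these counts.

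Messenger RNA of Dgcr8 itself was not measured in these libraries. The nearest readout was miR-1306, whose hairpin lies in a coding exon of Dgcr8 (GRCm38.p6 chromosome 16, 18284239 to 18284317, minus strand) and itself needs microprocessor processing, so that it does not separate gene dose from activity. Over the arms of the Dgcr8 hairpins, induced wild type had on average 123 counts, induced E518K 47.3 and the KO 0.333. As a share of the miRNA counts the order of the first 2 groups was the other way, with 0.00229% ± 0.000846 in wild type and 0.00382% ± 0.00367 in E518K (SD, n = 3), within the spread of the latter. Both untreated libraries had 0 counts, where the same clones had 57 (wild type) and 42 (E518K) after induction. The untreated totals were lower, so fewer counts could be seen there. They were 1421247 against 3394216 in wild-type clone 10 and 264507 against 1797240 in E518K clone 8. The libraries labelled KO had 1 count between them. miR-1306-3p was lower in KO than in induced wild type (log2 change −4.25 ± 1.10 SE, adjusted p = 0.00018). This call rests on 1 count in KO, so the size of the fall is uncertain. The miR-1306-3p mean in induced wild type was 18.1 CPM, where 0 counts allowed up to 12.8 to 18.3 CPM in a KO library. In E518K the value against wild type did not pass the test (0.97 ± 0.50, adjusted p = 0.078). It passed without wild-type clone 16 (1.75), without E518K clone 15 (1.42) and with total counts (1.45). With the scaling set by DGCR8-independent miRNAs this value was −1.83. miR-1306-5p was lower in E518K (−2.70 ± 0.79, adjusted p = 0.0015), a call that was lost without wild-type clone 16 (adjusted p = 0.079), without E518K clone 8 (0.071) and with DESeq2 (0.28). All 8 counts of the 5p arm in E518K came from clone 13. In KO the 5p arm was at 0 in every library (adjusted p against wild type = 0.00029, and 0.053 with DESeq2). The 5p mean in induced wild type, 14.7 CPM, lay within 12.8 to 18.3 CPM, so no fold can be given.

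The first comparison asked how E518K changes the miRNAs of embryonic stem cells relative to wild-type DGCR8. Induced E518K cells had less of the miR-290-295 cluster, the main miRNA cluster of mouse embryonic stem cells: 29.3% ± 3.06 of the miRNA counts (SD, n = 3) against 55.4% ± 5.24 in wild type. These shares count the reads of 4 pairs of its members 2 times, and with such miRNAs merged in all groups they were 19.2% ± 1.77 and 45.6% ± 4.54. The let-7 family, known for rising as stem cells differentiate, held 7.06% ± 1.15 against 0.904% ± 0.502, and the miR-183-96-182 cluster, first described in sensory organs, 26.1% ± 1.33 against 6.77% ± 0.314. DGCR8-independent miRNAs, which come from hairpins that bypass the microprocessor, held 1.24% ± 0.369 against 0.136% ± 0.0392. In all 4 groups the 3 E518K libraries lay outside the range of the 3 wild-type libraries, as in 10% of cases by chance. With miRNAs that count the same reads merged, let-7 held 8.09% against 1.12%, the miR-183-96-182 cluster 29.9% against 8.35% and DGCR8-independent miRNAs 1.41% against 0.167%. Shares of a total cannot show whether the whole miRNA pool changed. The medians of let-7 and of the miR-183-96-182 cluster turned from higher to lower (−0.59 and −0.94) when the DGCR8-independent list set the scaling.

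**Figure D1:**
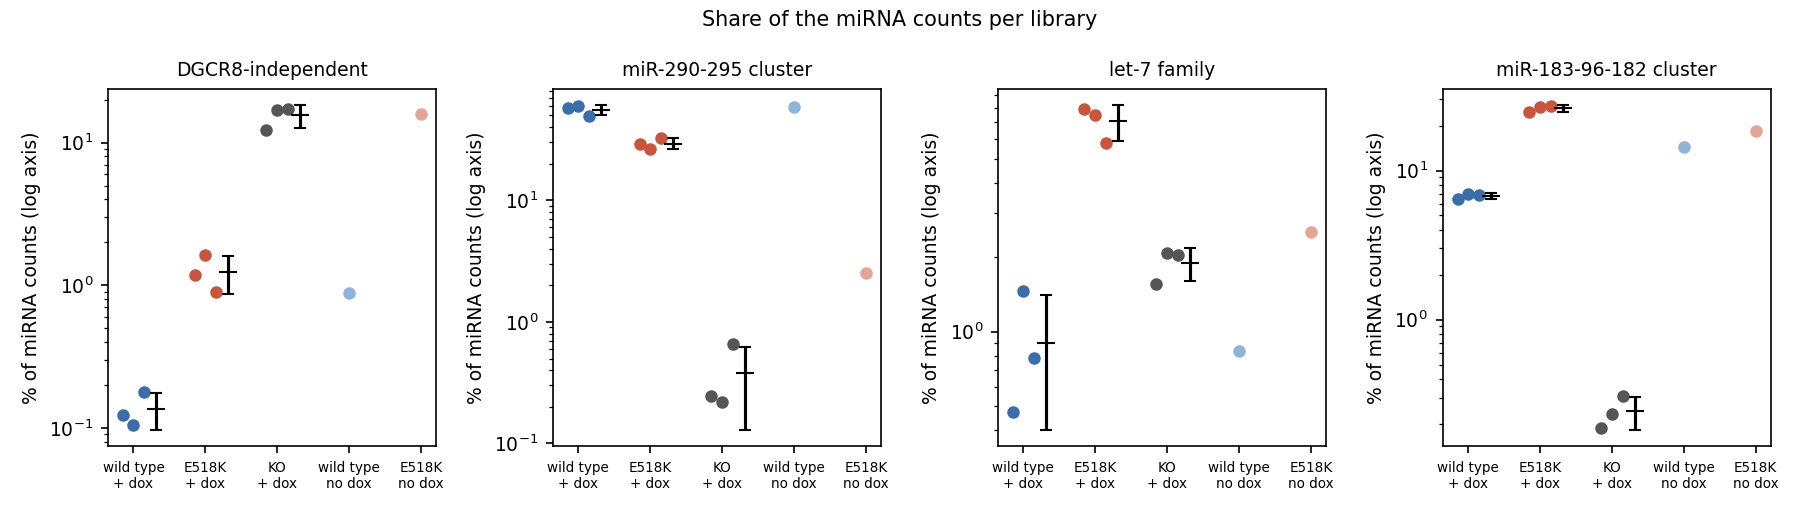
Share of the miRNA counts (%, log axis) held by 4 miRNA groups in each of the 11 libraries, 1 point per library, with the mean and SD of the groups of 3 libraries. DGCR8-independent miRNAs averaged 0.136% in induced wild type, 1.24% in induced E518K and 15.5% in KO, the miR-290-295 cluster 55.4%, 29.3% and 0.377%, let-7 0.904%, 7.06% and 1.89%, and the miR-183-96-182 cluster 6.77%, 26.1% and 0.243%. The miR-290-295 shares count some reads 2 times and were 45.6%, 19.2% and 0.220% with such miRNAs merged. When the DGCR8-independent list set the scaling instead, the let-7 and miR-183-96-182 medians were lower in E518K than in wild type (−0.59 and −0.94) and the median log2 change of the DGCR8-independent miRNAs was 0.01.

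With trimmed-mean (TMM) scaling within the miRNA counts, 206 miRNAs were higher and 258 lower in E518K, by edgeR's quasi-likelihood test, and 266 did not pass. The 2 groups of 3 libraries did not overlap for 471 of 730 miRNAs, where chance gives 10%. The balance of higher and lower calls depended on the scaling. Total counts gave 227 higher and 216 lower, DESeq2 size factors 177 and 269, the authors' pRPM scaling 183 and 250, the summed DGCR8-independent list 12 and 498, and the pRPM totals read as shares of a pool of reads 13 and 460. The median log2 change over all tested miRNAs was −0.14, 0.21, −0.29, −0.19, −2.90 and −2.56 under these scalings in the same order, so that a change given here is relative to a reference that the libraries alone do not fix. All 258 miRNAs lower with TMM were also lower under the list scaling, and all 12 that were higher under it were among the 206. Without wild-type clone 16 the balance turned to 250 higher and 164 lower.

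**Figure D2:**
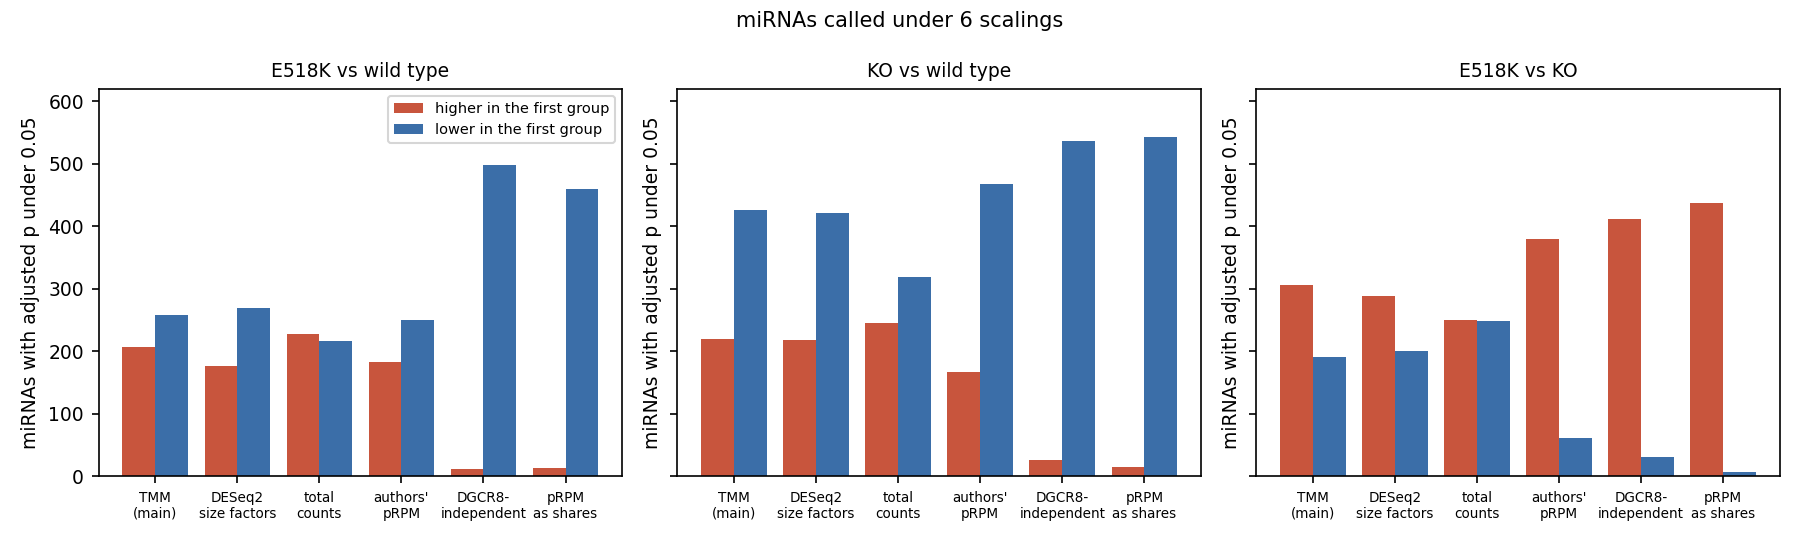
Number of miRNAs with an adjusted p under 0.05 (bars from 0), higher or lower in the first-named group, under 6 scalings and for 3 comparisons. For E518K against wild type the bars change from 206 higher and 258 lower with TMM to 12 and 498 when the DGCR8-independent list sets the scaling; for KO against wild type from 219 and 426 to 26 and 536; for E518K against KO from 306 and 191 to 412 and 30.

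Among the 8 most abundant miRNAs of induced wild type, both arms of miR-293 fell most in E518K. miR-293-5p went from 196809 ± 64277 to 10521 ± 2221 CPM (SD, n = 3 each; log2 change −4.23 ± 0.46 SE, adjusted p = 1.7e-17), and miR-293-3p changed by −3.55 ± 0.43. The hairpin lies on chromosome 7, 3220343 to 3220422, plus strand, opposite a UTR of Nlrp12. miR-292a-5p (Mir292, chromosome 7, 3219189 to 3219270) showed −0.97 ± 0.42 (adjusted p = 0.037), and its call was lost with total counts and with DESeq2. It was also lost without any of wild-type clones 10, 12 and 16 or E518K clones 8 and 13, with adjusted p from 0.14 to 0.51 in these 5 cases. miR-292b-3p, from a hairpin on the opposite strand, counted nearly the same reads as miR-292a-5p and cannot be separated from it. miR-7a-5p, abundant in endocrine and neural tissue, fell by 1.69 (SE 0.42, adjusted p = 0.00018), and its call was lost without wild-type clone 16 (−1.15, adjusted p = 0.061). Its hairpins lie in an intron of Hnrnpk (chromosome 13, 58392779 to 58392886) and on chromosome 7 (78888277 to 78888373). miR-182-5p (1.21 ± 0.41), miR-183-5p (1.97 ± 0.42) and miR-148a-3p (1.03 ± 0.41) rose with TMM scaling and turned to −1.56, −0.79 and −1.71 with the list scaling. The miR-148a-3p call was lost without wild-type clone 12 (adjusted p = 0.071) or E518K clone 15 (0.28) and with DESeq2 size factors (0.13), and its value was 1.64 without wild-type clone 16. Without that clone miR-183-5p was at 2.59 and miR-293-3p at −2.89. The hairpins of miR-182, miR-183 and miR-148a are on chromosome 6 at 30165918 to 30165992, 30169668 to 30169737 and 51269812 to 51269910, all on the minus strand.

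Ranked by the fitted fold, the first 8 miRNAs lower in E518K had 0 counts in every E518K library, so that their folds are known only as minimums, below measured falls such as that of miR-379-5p (−5.52). Against a floor of 6 counts per library, miR-130b-3p was at least 7.69-fold lower, miR-465b-5p 5.79-fold, miR-378a-5p 4.79-fold, miR-465c-5p 4.09-fold, miR-497a-3p 3.69-fold, miR-1948-5p 3.61-fold, miR-452-5p 3.20-fold and miR-3086-5p 2.98-fold, each a minimum. miR-465b and miR-465c come from near-identical hairpins on chromosome X, so their counts are uncertain. Ranked in the same way, the first 8 higher were miR-6516-5p (log2 change 4.44 ± 0.73), miR-1981-3p (4.09 ± 0.43), miR-136-5p (3.89 ± 0.43), miR-3071-3p (3.81 ± 0.43), miR-8114 (3.73 ± 0.57), let-7a-5p (3.68 ± 0.43), miR-3068-3p (3.67 ± 0.42) and miR-1981-5p (3.67 ± 0.45). Every one of these 8 stayed above 0 under the other scalings. With the list scaling miR-6516-5p and miR-8114 no longer passed (adjusted p = 0.054 and 0.12). The 6 counts of miR-6516-5p in wild type all came from clone 16, and its value was 3.73 without wild-type clone 12 and 3.47 without E518K clone 13. Without wild-type clone 16 miR-136-5p was at 4.80, miR-3071-3p at 4.73, miR-8114 at 4.40 and miR-3068-3p at 4.36, and without wild-type clone 12 let-7a-5p was at 4.35. Mir1981 fills an intron of Marc2 (chromosome 1, 184822407 to 184822488). Mir136 (chromosome 12, 109595327 to 109595388) and Mir3071 overlap on opposite strands at a coding exon of Rtl1, so that miR-136-5p and miR-3071-3p share reads. The other arm of Mir136, miR-136-3p, went the other way. It changed by −1.09 on the log2 scale, from 718 CPM in induced wild type to 337 in E518K. The hairpin of let-7a-5p, Mirlet7a-1, is on chromosome 13, 48538179 to 48538272; other let-7a hairpins may add to its count. In the plot of single miRNAs, let-7a-5p ran from 550 to 2605 in wild type and from 13562 to 22781 in E518K.

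**Figure D3:**
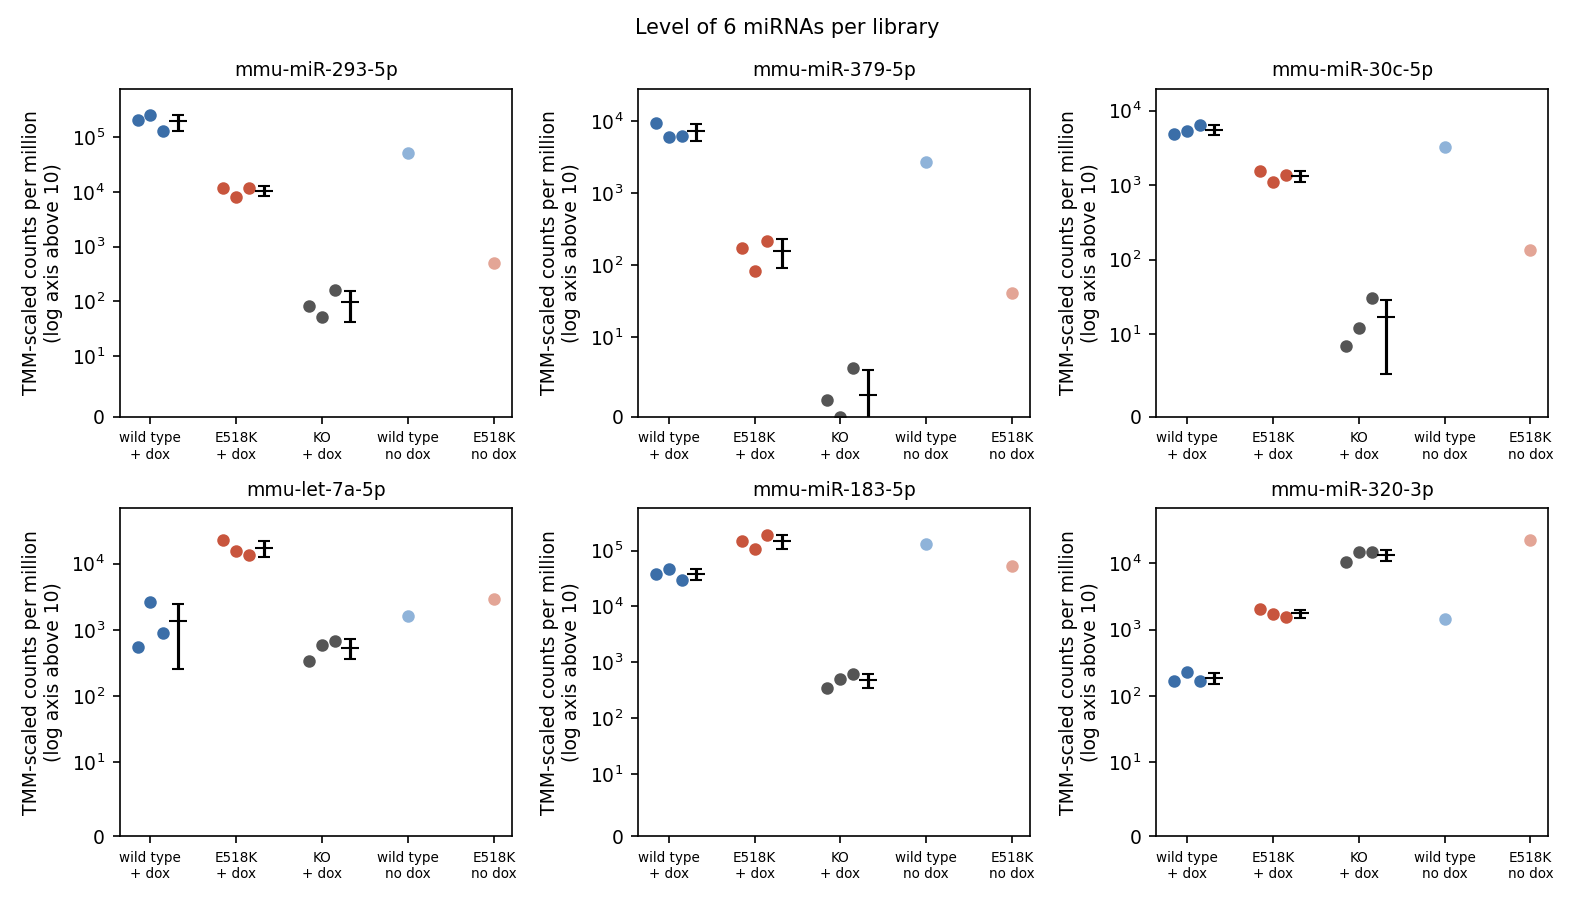
TMM-scaled CPM of 6 miRNAs in each library (log axis above 10), 1 point per library, with the mean and SD of the groups of 3 libraries. miR-293-5p lay between 127700 and 254804 in induced wild type, between 7965 and 11977 in induced E518K and between 51.1 and 159 in KO, while miR-320-3p rose in the same order (168 to 230, 1536 to 2021 and 10592 to 15024). The level of let-7a-5p, higher in E518K here, stayed higher under the other scalings, whereas miR-183-5p turned lower in E518K (−0.79) when the DGCR8-independent list set the scaling.

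Of 12 tested DGCR8-independent miRNAs 10 rose in E518K with TMM scaling, also when adjusted over the list alone. Their median log2 change was 2.75, which went to 0.01 under their own scaling and to 0.33 with the pRPM totals read as shares. miR-320-3p (chromosome 14, 70443510 to 70443591), whose short hairpin is cut by Dicer alone, rose by 3.22 on the log2 scale (SE 0.41). miR-484 (chromosome 16, 14159626 to 14159692) changed by 3.03, miR-877-5p and miR-877-3p, from a short intron of Abcf1 (chromosome 17, 35960730 to 35960814), by 3.49 and 2.87, and miR-1983 (chromosome 13, 21896918 to 21897049) by 3.22. miR-702-5p and miR-702-3p showed 3.58 and 2.62, miR-1291 2.16, and miR-1839-5p and miR-1839-3p 2.06 and 1.41. miR-1224-5p (0.60, adjusted p = 0.56) and miR-320-5p (−0.87, adjusted p = 0.62) did not pass, both with mean levels near or below 3 CPM in either group. The miR-1839-3p call was lost without wild-type clone 10 or 12 or E518K clone 8 (adjusted p = 0.067, 0.18 and 0.12), and its value was 2.23 without wild-type clone 16. That of miR-877-3p was lost without E518K clone 13 (0.068) and with only the 2 groups in the fit (0.074). Without wild-type clone 16 the values were 4.11 for miR-877-5p, 3.96 for miR-1983, 3.83 for miR-320-3p, 3.81 for miR-484, 3.63 for miR-702-3p, 3.48 for miR-877-3p, 2.89 for miR-1291 and 2.77 for miR-1839-5p. That of miR-702-3p was 1.98 without wild-type clone 12, and that of miR-877-3p 3.67 without E518K clone 8 and 2.23 without E518K clone 15. The list differed from all other tested miRNAs by camera with a preset correlation (adjusted p = 0.0020), and not with an estimated correlation (adjusted p = 0.51). With the latter, 0 of 16 lists passed by camera in this comparison, 0 also at an unadjusted p under 0.05, whereas fry called 12.

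Let-7 showed 11 of 13 members higher and 1 lower with TMM scaling, the same when adjusted over the list alone. Their median log2 change of 2.19 turned to −0.59 with the list scaling and −0.23 with the pRPM totals read as shares. let-7f-5p changed by 2.85 ± 0.42 (3.59 without wild-type clone 12) and let-7g-5p by 0.85 ± 0.38 (adjusted p = 0.042). The let-7g-5p call was lost without wild-type clone 10 or E518K clone 8 or 15 (adjusted p = 0.28, 0.074 and 0.059) and with DESeq2 (0.088). Its value was 1.45 without wild-type clone 12 and 1.30 without wild-type clone 16. All 6 arms of the miR-183-96-182 cluster rose, also adjusted over the list alone, with a median of 1.84 that turned to −0.94 and −0.57 under those 2 scalings. Camera with a preset correlation called both groups (adjusted p = 0.0020 and 0.0091), and the estimated correlation did not (adjusted p = 0.63 and 0.51). The Dlk1-Dio3 imprinted cluster, a large set of miRNAs expressed from the maternal chromosome 12, had 48 members lower and 13 higher of 86, the same adjusted over the list alone. It had a median of −1.57 (−1.29 with members at 0 set to their bound) that stayed below 0 under every scaling. Its most abundant member, miR-379-5p (chromosome 12, 109709060 to 109709125), fell by 5.52 on the log2 scale (SE 0.45, adjusted p = 2.6e-29), and by 4.82 without wild-type clone 16. By contrast, miR-541-5p showed −0.33 (adjusted p = 0.43), with 0.36 without wild-type clone 16. Within the Sfmbt2 intron cluster, a repeated miRNA array on chromosome 2, 14 of 27 fell and 2 rose, the same adjusted over the list alone. The median was −1.62 (−0.97 at the bound), below 0 under every scaling. The mean share of the counts went the other way, with 0.345% ± 0.132 in E518K and 0.210% ± 0.0465 in wild type (SD, n = 3), and the libraries overlapped. Against the direction of the median, the most abundant member miR-669c-5p showed 1.10 ± 0.38 (adjusted p = 0.0069, with −1.68 under the list scaling and 1.71 without wild-type clone 16). Its call was lost without wild-type clone 10 or 12 or E518K clone 8 (0.052, 0.11 and 0.089). miR-466c-5p showed −0.15 (adjusted p = 0.75; 0.27 with total counts, 0.47 without wild-type clone 16 and 0.14 without E518K clone 8). Camera called the Dlk1-Dio3 cluster (adjusted p = 0.0041, and 0.77 with an estimated correlation) and the Sfmbt2 cluster (adjusted p = 0.036, and 0.51 with an estimated correlation). The Sfmbt2 call was lost without wild-type clone 12 or 16 or E518K clone 8 or 15 (adjusted p = 0.061 to 0.14) and with total counts (0.060).

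For 11 other tested lists camera made no call in E518K. The miR-290-295 cluster, whose 18 members include 4 pairs that count the same reads, had 9 lower (4 adjusted over the list alone), with a median of −0.60 that stayed below 0 under every scaling. The miR-302-367 cluster had 4 of 9 lower, the miR-200 family, known for keeping epithelial identity, 4 of 7, and the miR-30 family 3 of 11. The miR-15-16 family, regulators of the cell cycle, had 9 of 14 lower and 1 higher (camera adjusted p = 0.054). These 4 groups had medians below 0 under every scaling and the same counts adjusted over the list alone. The 1 higher member of the miR-15-16 family, miR-16-1-3p, had its highest mean level in both groups and went from 2197 ± 447 to 6514 ± 2473 CPM (log2 change 1.57 ± 0.38, adjusted p = 0.00013). Against the direction of its median, the family held 0.709% ± 0.00445 of the E518K counts and 0.315% ± 0.105 of the wild-type counts, or 0.814% ± 0.0171 and 0.386% ± 0.116 with miRNAs that count the same reads merged. With the list scaling all 14 members fell. In the miR-17-92 clusters 5 of 28 rose and 8 fell (7 adjusted over the list alone), with a median of 0.20 and a mean of −0.13. This median turned to −2.59 with the list scaling and −2.22 with pRPM totals as shares. Of the 4 tested in the miR-34-449 family 0 passed by edgeR, as over the list alone and at an unadjusted p under 0.05, with a median of 0.51 that turned to −2.26 and −1.99. Among markers of other cell types, 1 of 4 muscle miRNAs rose and 1 fell (0 and 1 adjusted over the list alone; median 0.49, −2.26 with the list scaling). Among neural ones 2 of 12 rose and 5 fell, and 2 of 9 blood ones rose and 4 fell, with medians of −1.11 and −0.79 below 0 under every scaling (−0.27 for the blood markers with members at 0 set to their bound). Of 23 fibroblast and mesenchymal markers 5 fell and 0 rose (also over the list alone), with a median of −0.13 that was 0.25 with total counts. The liver miRNA miR-122-5p rose (log2 change 2.46, adjusted p = 0.00015; −0.26 with the list scaling) from a mean of 2.17 to 12.9 CPM.

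Over all tested miRNAs outside the DGCR8-independent list, the median per library of the log2 ratio to the wild-type mean was −0.283 ± 0.183 in E518K (SD, n = 3), −0.00831 ± 0.0505 in wild type and −2.93 ± 0.147 in KO. The difference between E518K and wild type was −0.275 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows), and without wild-type clone 16 it was 0.394. For the DGCR8-independent list the medians were 2.43 ± 0.0817 in E518K, 0.0733 ± 0.174 in wild type and 4.45 ± 0.616 in KO, a difference of 2.35 between E518K and wild type (exact permutation p = 0.1). With the summed list as scaling the difference was −2.80 for other miRNAs and −0.106 for the list.

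The second comparison measured loss of DGCR8 against induced wild-type DGCR8. Most miRNAs that dominate embryonic stem cells were nearly gone in KO. The miR-290-295 cluster held 0.377% ± 0.247 of the counts (SD, n = 3), against 55.4% ± 5.24 in wild type. It held 0.220% ± 0.136 and 45.6% ± 4.54 with miRNAs that count the same reads merged. All 18 of its members, which are 14 after such merging, fell. Members of the miR-17-92 clusters, which promote proliferation, fell in 27 of 28 cases. DGCR8-independent miRNAs held 15.5% ± 2.78 of the KO counts, and 11 of 12 rose with TMM scaling (median 4.79), while their medians were −0.49 under their own scaling and −1.003 with pRPM totals as shares. With TMM 219 miRNAs were higher and 426 lower. Total counts gave 245 and 319, DESeq2 size factors 218 and 421, the pRPM scaling 167 and 468, the list scaling 26 and 536 and pRPM totals as shares 15 and 543. All 426 lower miRNAs were also lower with the list scaling. The median over all tested miRNAs was −3.54 with TMM, −2.03 with total counts and −8.23 with the list scaling.

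Among the 8 most abundant wild-type miRNAs, miR-293-5p fell to 97.7 ± 55.3 CPM in KO (log2 change −10.98 ± 0.62 SE, adjusted p = 6.2e-56) and miR-293-3p changed by −10.69. miR-292a-5p and the read-sharing miR-292b-3p changed by −8.52, miR-7a-5p by −8.85, miR-182-5p by −6.54, miR-148a-3p by −6.46 and miR-183-5p by −6.28, each below every wild-type library. Ranked by the fitted fold, the first 8 decreases were in miRNAs with 0 counts in all KO libraries, whose minimums lie below measured falls such as that of miR-293-5p. These were miR-363-3p (at least 254-fold lower; chromosome X, 52741693 to 52741767), miR-20b-5p (at least 222-fold; chromosome X, 52742113 to 52742192), miR-341-3p (207), miR-106a-5p (141), miR-134-5p (102), miR-411-5p (99.4), miR-323-3p (98.1) and miR-18b-5p (81.5). Among these, miR-363, miR-20b, miR-106a and miR-18b belong to the X-linked miR-106a-363 cluster and miR-341, miR-134, miR-411 and miR-323 to the Dlk1-Dio3 cluster. The first 8 increases were in miRNAs with 0 counts in all induced wild-type libraries, again given as minimums, which lie below measured rises such as that of miR-877-5p (6.51). These were miR-6541 (at least 63.8-fold higher; in an intron of Wdfy2, chromosome 14, 62865542 to 62865651), miR-3569-5p (58.9; chromosome 7, 30589380 to 30589437), miR-6945-3p (48.5; in a UTR of Pdlim7, chromosome 13, 55507625 to 55507692), miR-344f-3p (47.5), miR-7070-5p (30.9), miR-6932-3p (29.4), miR-6967-3p (29.0) and miR-6938-3p (17.5).

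All 18 members of the miR-290-295 cluster (median log2 change −8.22), 27 of 28 in the miR-17-92 clusters (−8.29), 7 of 7 in the miR-200 family (−8.03), 11 of 11 in the miR-30 family (−6.44), 6 of 6 in the miR-183-96-182 cluster (−6.87), 26 of 27 in the Sfmbt2 cluster (−7.64, with 1 higher) and 82 of 86 in the Dlk1-Dio3 cluster (−8.66, with 3 higher) fell, with the same counts adjusted over the list alone and medians below 0 under every scaling. With members at 0 set to their bound, these medians were −8.05, −4.00, −4.80, −3.08, −5.49, −1.71 and −3.25. Examples are miR-25-3p (−7.50) and miR-92a-3p (−8.35), miR-200b-3p (−8.35) and miR-200a-3p (at least 27.9-fold lower), miR-30d-5p (−4.16) and miR-30c-5p (−8.41), miR-669c-5p (−5.45) and miR-466c-5p (at least 14.7-fold lower), and miR-379-5p (−11.37) and miR-541-5p (−9.64). Of the DGCR8-independent miRNAs, miR-320-3p rose by 6.16, miR-877-5p by 6.51, miR-877-3p by 6.52, miR-702-5p by 5.40, miR-1983 by 5.23, miR-1291 by 4.91, miR-1839-5p by 4.68, miR-484 by 4.45, miR-702-3p by 4.14, miR-1839-3p by 3.87 and miR-1224-5p by 2.11 on the log2 scale, 11 also adjusted over the list alone. Under the list scaling 8 of the 12 tested had values below 0. The miR-1224-5p call (adjusted p = 0.032) was lost without KO library 1 (0.086) or wild-type clone 16 (0.12) and with the pRPM scaling (0.76). miR-320-5p did not pass (1.65, adjusted p = 0.27).

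Camera with a preset correlation called these 8 groups: DGCR8-independent (adjusted p = 6.8e-06), miR-290-295 and miR-17-92 (5.2e-05 each), Dlk1-Dio3 (1.7e-08), Sfmbt2 (0.0028), miR-30 (0.012), miR-183-96-182 (0.036) and miR-200 (0.0496). With an estimated correlation none passed, at adjusted p = 0.32 for miR-30, 0.33 for miR-183-96-182 and 0.28 for the other 6. At an unadjusted p under 0.05 that count was 1, and fry called 12 of 16 lists. The miR-200 call was lost without any KO library or wild-type clone 10 or 16 (adjusted p = 0.055 to 0.090). Of the uncalled groups, 14 of 14 in the miR-15-16 family (adjusted p = 0.052), 8 of 9 in the miR-302-367 cluster, 11 of 12 neural and 9 of 9 blood markers fell, also adjusted over the list alone. Their medians were below 0 under every scaling, but with members at 0 set to their bound they were −1.78, −2.80, −2.27 and 0. Let-7 had 3 members higher and 7 lower of 13 (2 and 6 adjusted over the list alone). Its median of −1.33 was −0.22 with members at 0 set to their bound and 0.36 with total counts, while camera gave the direction up relative to other miRNAs. Of 4 in the miR-34-449 family 2 rose and 1 fell (median 1.84, −3.27 with the list scaling). Of 4 muscle markers 2 rose and 1 fell (median 2.23, mean −0.67, −2.90 with the list scaling), with the same counts over the list alone. Of 23 fibroblast and mesenchymal markers 8 rose and 8 fell, also over the list alone (median 0.47, mean −0.33, −4.82 with the list scaling). miR-122-5p rose by 4.97 (−0.16 with the list scaling).

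The third comparison asked what induced E518K restores over the KO. E518K cells held 148802 CPM of miR-183-5p against 491 in KO and 143964 of miR-292a-5p against 768. All 18 members of the miR-290-295 cluster, 27 of 28 in the miR-17-92 clusters and 6 of 6 in the miR-183-96-182 cluster rose. DGCR8-independent miRNAs went the other way with TMM scaling, 10 of 12 lower with a median of −2.49, which was −0.02 under their own scaling and 0.79 with pRPM totals as shares. With TMM 306 miRNAs were higher and 191 lower in E518K, against 250 and 249 with total counts, 289 and 200 with DESeq2 size factors, 380 and 61 with the pRPM scaling, 412 and 30 with the list scaling and 438 and 6 with pRPM totals as shares. The median change was 1.35, 0.18, 1.17, 3.08, 3.26 and 4.03. Without KO library 1 the split was 311 to 138 and without E518K clone 15 it was 342 to 124.

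Of the most abundant wild-type miRNAs, miR-183-5p rose by 8.25 ± 0.56 on the log2 scale (adjusted p = 4.0e-42), miR-182-5p by 7.74, miR-292a-5p and miR-292b-3p by 7.55, miR-148a-3p by 7.49, miR-7a-5p by 7.17, miR-293-3p by 7.14 and miR-293-5p by 6.76, above every KO library. Largest among miRNAs at 0 in all KO libraries were miR-20b-5p (at least 176-fold higher), miR-363-3p (111), miR-335-3p (56.0), miR-106a-5p (50.5), miR-294-5p (29.3), miR-302b-3p (28.3), miR-182-3p (25.1) and miR-708-5p (22.0). Lower in E518K, with 0 counts there, were miR-7038-5p (at least 3.45-fold), miR-6929-3p (2.31) and miR-7677-3p (2.18), followed by 3 miRNAs with 6 counts or fewer in each E518K library, for which levels are given in place of a fold. These were miR-6945-3p (0.991 ± 0.876 CPM in E518K and 95.1 ± 32.6 in KO), miR-7666-3p (1.09 ± 1.89 and 51.8 ± 5.87) and miR-7648-3p (2.34 ± 2.51 and 81.1 ± 15.7). miR-10a-5p was lower by a log2 change of −4.90 ± 0.48. All 5 counts of miR-7666-3p in E518K came from clone 8. miR-5134-3p also passed (adjusted p = 0.0066, lost without E518K clone 15 at 0.096), at or under 6 counts in each of these libraries. Of these 8, miR-6945-3p, miR-7038-5p and miR-10a-5p passed under every scaling.

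Camera with a preset correlation called 10 of 16 lists between E518K and KO. With an estimated correlation it called 0 (adjusted p from 0.26 to 0.59 for these 10), with 1 list at an unadjusted p under 0.05, whereas fry called 13. In addition to the 3 clusters above, 10 of 13 let-7 members, 6 of 7 in the miR-200 family, 10 of 11 in the miR-30 family, 8 of 9 in the miR-302-367 cluster, 19 of 27 in the Sfmbt2 cluster and 67 of 86 in the Dlk1-Dio3 cluster (69 adjusted over the list alone, with 2 lower) rose. The others had the same counts over the list alone, and all had medians above 0 under every scaling. Median log2 changes were 7.35 for miR-290-295, 8.88 for miR-17-92, 8.35 for miR-183-96-182, 3.31 for let-7, 6.38 for miR-200, 3.62 for miR-30, 7.31 for miR-302-367, 5.50 for Sfmbt2 and 6.85 for Dlk1-Dio3. With members at 0 set to their bound they were 6.95, 3.604, 7.59, 1.60, 3.50, 2.54, 1.57, 0.06 and 1.52 in the same order. Examples are miR-92a-3p (9.15) and miR-25-3p (5.60), let-7f-5p (3.31) and let-7g-5p (3.38), miR-200b-3p (5.30) and miR-200a-3p (at least 11.3-fold higher), miR-30c-5p (6.34) and miR-30d-5p (3.62), miR-302a-5p (3.91), miR-669c-5p (6.55) and miR-466c-5p (at least 13.3-fold higher), and miR-541-5p (9.31) and miR-379-5p (5.85). Adjusted p ranged from 3.4e-08 for Dlk1-Dio3 to 0.035 for let-7 and miR-200. Without KO library 2 the calls of miR-302-367, let-7, miR-200 and Sfmbt2 were lost (adjusted p = 0.070, 0.083, 0.077 and 0.070). Let-7 was also lost without KO library 3 or E518K clone 8 or 13, and miR-200 without KO library 3 or E518K clone 13.

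The DGCR8-independent members lower in E518K than in KO were miR-877-3p (−3.65), miR-877-5p (−3.02), miR-320-3p (−2.94), miR-1291 (−2.75), miR-1839-5p (−2.61), miR-1839-3p (−2.46), miR-1983 (−2.02), miR-702-5p (−1.82), miR-702-3p (−1.52) and miR-484 (−1.42), 10 also adjusted over the list alone. Without E518K clone 15 the calls of miR-702-3p, miR-702-5p and miR-484 were lost (adjusted p = 0.60, 0.15 and 0.54), and without KO library 1 those of miR-702-3p, miR-702-5p and miR-877-3p (0.16, 0.092 and 0.052). The value of miR-484 was −0.93 without KO library 1, −2.15 without KO library 2 and −2.23 without E518K clone 13. That of miR-702-3p was −2.37 without KO library 3, −2.36 without E518K clone 8 and −2.33 without E518K clone 13, and that of miR-1983 was −1.07 without E518K clone 15. miR-1224-5p (−1.51, adjusted p = 0.16) and miR-320-5p (adjusted p = 0.19, at 2 counts or fewer in each library) did not pass. miR-1306-3p, with 1 count over the KO libraries, rose by 5.22 (SE 1.03) and miR-1306-5p did not pass (adjusted p = 0.13) except without E518K clone 15. Of the lists without a call, 7 of 14 in the miR-15-16 family rose and 1 fell, and 8 of 12 neural and 3 of 9 blood markers rose. In each of the miR-34-449 and muscle groups 1 of 4 rose and 1 fell, and 5 of 23 fibroblast markers rose and 8 fell. All of these counts were the same over the list alone. For the miR-34-449, muscle and fibroblast groups the medians were −1.81, −0.63 and −0.88 and turned to 0.63, 1.81 and 1.49 with the list scaling; for the muscle group the mean was 1.19. miR-122-5p was lower by 2.51 on the log2 scale, and 0.75 higher with pRPM totals as shares.

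Changes against wild type in E518K and in KO overlapped. With TMM 235 miRNAs were lower and 144 higher in both, 48 were higher in E518K and lower in KO, and 1 was lower in E518K and higher in KO. Independent lists of these sizes would share 151 lower and 61.8 higher. In addition, 50 simulations drew every library from the wild-type means, with the drawn wild-type libraries shared by both comparisons. They shared 0 calls, or 1.84 lower and 2.90 higher at an unadjusted p under 0.05 by edgeR, where the observed counts were 242 and 152. With no changed miRNAs hardly any call was possible, so the 0 was set in advance. It gives no expectation for groups that do differ from wild type. Across 445 miRNAs the covariance of both sets of log2 changes was 7.89, against 0.247 in the simulations. Pearson's r was 0.647 against 0.248, across miRNAs, which are not independent replicates. Both comparisons use the same 3 wild-type libraries, which cannot be split into parts of 2, so part of the excess may come from shared controls. For the covariance this part was small in the simulations, which shared these controls and reached at most 0.434. The overlap counts are not bounded in this way. The count lower in both was 155 with total counts and 485 with the list scaling, and the count higher in both 9 with the list scaling.

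The untreated libraries were made to measure leaky expression of the vectors. Without doxycycline, wild-type clone 10 already had the miR-290-295 cluster at 58.6% of its counts (95% exact binomial interval 58.5 to 58.7), against 0.377% ± 0.247 in the induced KO libraries (SD, n = 3). With miRNAs that count the same reads merged these were 43.8% (43.7 to 43.9) and 0.220% ± 0.136. DGCR8-independent miRNAs were at 0.880% (0.858 to 0.902). Against KO, 316 miRNAs were higher and 98 lower, with the single library assumed to vary like the other groups. Such calls compare this library with the KO libraries of 1 clone, not the conditions, and have no replicate check of the untreated cells. All KO libraries had doxycycline and this library had none, so the vector and doxycycline itself cannot be told apart here. Total counts gave 209 and 215, DESeq2 size factors 283 and 135, the pRPM scaling 336 and 34, the list scaling 401 and 13, and pRPM totals as shares 406 and 2. miR-293-3p was higher by 9.72 ± 0.62 on the log2 scale, miR-292a-5p and miR-292b-3p by 9.45, miR-293-5p by 9.06, miR-148a-3p by 8.45, miR-183-5p by 8.04, miR-182-5p by 7.91 and miR-7a-5p by 6.15. The first 5 by fitted fold had 0 counts in the KO, and their folds, minimums below the measured rise of miR-293-3p, were at least 117 for miR-136-3p and for the overlapping miR-3071-5p, 68.2 for miR-20b-5p, 61.1 for miR-335-3p and 37.1 for miR-434-3p. Among those lower, the first 5 by fitted fold were at 0 in untreated wild type, with minimums of 7.03 for the muscle miRNA miR-206-3p, 5.92 for miR-7666-3p, 4.42 for miR-7655-5p, 3.83 for miR-6988-3p and 2.79 for miR-8092. With pRPM totals as shares the last 4 no longer passed (adjusted p = 0.064 to 0.23). Without KO library 2 the split was 234 to 145, and without KO library 3 it was 238 to 153.

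In untreated E518K clone 8 the miR-290-295 cluster held 2.51% of the counts (95% exact binomial interval 2.43 to 2.60), or 1.45% (1.39 to 1.52) with miRNAs that count the same reads merged, and DGCR8-independent miRNAs 16.0% (15.8 to 16.2). The miR-183-96-182 cluster held 18.3%, against 0.243% ± 0.0607 in KO. Here 111 miRNAs were higher and 1 lower than in KO, with the single library again assumed to vary like the other groups and no replicate check of the untreated cells, so that these calls too compare libraries, not conditions. As above, only the KO libraries had doxycycline. In all 69 passed with total counts, 78 with DESeq2 size factors, 99 with the pRPM scaling, 78 with the list scaling and 104 with pRPM totals as shares, of which at most 6 were lower. The count was 196 with miRNAs that count the same reads merged and 223 with counts divided by 2, and 64 without KO library 2 and 66 without KO library 3. miR-182-5p was higher by 7.15 ± 0.57 on the log2 scale, miR-183-5p by 6.78, miR-148a-3p by 5.74, miR-7a-5p by 4.58 and miR-292a-5p and miR-292b-3p by 3.52. miR-293-5p (2.39, adjusted p = 0.00027) and miR-293-3p (2.53, adjusted p = 0.00038) also passed. Neither did so without KO library 2 (0.25 and 0.40) or with the list scaling (0.085 and 0.095), and the 3p arm not without KO library 3 (0.076). The first 5 by fitted fold were at 0 in the KO and are known only as minimums, namely miR-182-3p (at least 7.18-fold), miR-330-5p (6.21), miR-7b-5p (3.88), miR-96-3p (3.49) and miR-335-3p (3.11). The 1 miRNA lower was miR-151-3p (−1.74, adjusted p = 0.045), lost without KO library 1 (0.18), without a filter (0.060) and with the pRPM scaling (0.087), and at −2.69 without KO library 3. Of the fixed lists, 6 of 6 in the miR-183-96-182 cluster, 12 of 18 in miR-290-295 and 12 of 28 in miR-17-92 were higher, with medians above 0 under every scaling. Of 12 DGCR8-independent miRNAs 0 passed by edgeR, and 1 was higher at an unadjusted p under 0.05.

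Within each clone, induction could be compared for 1 library against 1, with no test. In wild-type clone 10, miR-25-3p was 11.1-fold higher with doxycycline in CPM of all miRNA counts, miR-7a-5p 9.19-fold and miR-293-5p 4.97-fold, and miR-292a-5p went from 257765 to 194331. In E518K clone 8, miR-20b-5p was 58.6-fold higher with doxycycline, miR-25-3p 20.5-fold, miR-293-5p 16.2-fold, miR-292a-5p 11.5-fold and let-7a-5p 5.50-fold. The fold of miR-20b-5p is imprecise, since it rests on 11 counts without doxycycline, against 84 for miR-25-3p. DGCR8-independent miR-320-3p was 6.96-fold higher without doxycycline in wild-type clone 10 (701 CPM, 95% exact binomial interval 641 to 765, against 101, 86.2 to 117) and 15.6-fold in E518K clone 8 (26737, 25874 to 27620, against 1718, 1634 to 1806). These folds are relative to the total of miRNA counts in each library, and the intervals cover counting error only. The series has no KO library without doxycycline, so effects of doxycycline itself cannot be told apart from those of induced DGCR8.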

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

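All comparisons of scalings here were chosen after the result was seen. For 6 of the miRNA groups with at least 100 counts in each of the 4 libraries, the share of the miRNA counts moved in opposite directions with doxycycline in wild-type clone 10 and in E518K clone 8. Each change compares 1 library with 1 library of the same clone, and the difference between genotypes was not tested. As log2 of the share with over the share without doxycycline, the miR-290-295 cluster showed −0.033 in wild type and 3.53 in E518K, let-7 −0.81 and 1.65, the miR-15-16 family −1.50 and 1.66, the miR-30 family −0.90 and 1.97, the miR-183-96-182 cluster −1.17 and 0.43, while the fibroblast and mesenchymal markers showed 0.26 and −1.41. With the summed DGCR8-independent list as scaling in place of the total, the first 5 groups were higher with doxycycline in both clones. Their values were 2.79 and 7.29 for miR-290-295, 2.02 and 5.42 for let-7, 1.32 and 5.43 for miR-15-16, 1.93 and 5.73 for miR-30, 1.66 and 4.19 for miR-183-96-182. The fibroblast markers were higher as well (3.09 and 2.36), and with pRPM totals as shares these 6 groups were likewise higher in both clones. With the pRPM scaling miR-290-295 (0.42 and 5.83) and the fibroblast markers (0.71 and 0.90) were higher in both. Opposite directions remained with it for let-7 (−0.36 and 3.95), miR-15-16 (−1.05 and 3.97), miR-30 (−0.44 and 4.27) and miR-183-96-182 (−0.72 and 2.73), and the miR-34-449 family also showed them (−0.13 and 1.17). With TMM scaling the fibroblast markers fell in both clones (−0.05 and −0.92), the first 5 kept opposite directions and the Sfmbt2 intron cluster also had them (−0.29 and 1.69). With miRNAs that count the same reads merged the miR-290-295 cluster no longer moved in opposite directions (0.094 in wild type and 3.70 in E518K), whereas the other 5 did so, as did the Sfmbt2 intron cluster (−0.11 and 1.37). The muscle markers, with 41 counts in untreated E518K, also differed in sign as shares (0.33 in wild type and −0.25 in E518K), and not with TMM scaling (0.018 and 0.24).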

How the results depend on the processing

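Changes of sign came from scaling and from leaving out a library, and an estimated correlation ended every list call of camera. The cause was not tested except where the scaling itself fixes it, as for the DGCR8-independent list under its own scaling. For single miRNAs and lists 2641 values kept their direction and side of the threshold, 171 lost and 18 gained a call, and 64 changed sign; of counts and medians 111 stayed close, 26 moved and 2 changed sign. Alternatives chosen after seeing the data were the pRPM scaling, the pRPM totals as shares, merged miRNAs, halved counts, and total and list scaling of the fixed lists. The planned scalings and results from piRNA counts were not run, since that file repeated the pRPM values. No paired analysis was possible because the groups compared share fewer than 2 clone numbers. Over all alternatives run with every library, calls ranged from 393 to 510 in E518K against wild type, from 534 to 727 in KO against wild type, from 374 to 512 in E518K against KO and from 370 to 424 in untreated wild type against KO. The number of miRNA counts in the KO libraries set the lowest KO level that could be read, 12.8 to 18.3 CPM per library.

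With total counts miR-466c-5p in E518K against wild type was 0.27, untreated E518K against KO had 69 calls, the median ratio of E518K to wild type was −0.0712 for other miRNAs and 2.61 for the DGCR8-independent list, and 155 miRNAs were lower in both E518K and KO.

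With the DGCR8-independent list as scaling, values in E518K against wild type were −1.56 for miR-182-5p, −0.79 for miR-183-5p, −1.71 for miR-148a-3p, −2.14 for miR-1224-5p, −1.35 for miR-1839-3p, −0.12 for miR-702-3p, −0.70 for miR-1839-5p, −0.60 for miR-1291, −1.83 for miR-1306-3p, −1.94 for let-7g-5p and −1.68 for miR-669c-5p. In KO against wild type they were −3.05 for miR-1224-5p, −1.44 for miR-1839-3p, −1.03 for miR-702-3p, −0.85 for miR-484, −0.57 for miR-1839-5p, −3.29 for miR-320-5p, −0.42 for miR-1291 and −0.048 for miR-1983, and in E518K against KO 0.92 for miR-1224-5p, 0.0899 for miR-1839-3p, 0.90 for miR-702-3p, 1.08 for miR-484, 0.62 for miR-702-5p and 0.48 for miR-1983. The median ratio was −2.80 for other miRNAs and −0.106 for the list, and 485 miRNAs were lower and 9 higher in both E518K and KO.

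With the pRPM scaling miR-320-5p in KO against wild type was −0.20, and in E518K against KO miR-1224-5p was 0.16, miR-702-3p 0.32 and miR-484 0.49. With pRPM totals as shares, values in E518K against wild type were −1.19 for miR-182-5p, −0.46 for miR-183-5p, −1.44 for miR-148a-3p, −1.84 for miR-1224-5p, −1.10 for miR-1839-3p, −0.39 for miR-1839-5p, −0.25 for miR-1291, −1.36 for miR-1306-3p, −1.46 for let-7g-5p and −1.28 for miR-669c-5p. In KO against wild type they were −3.46 for miR-1224-5p, −1.96 for miR-1839-3p, −1.65 for miR-702-3p, −1.38 for miR-484, −0.18 for miR-702-5p, −1.11 for miR-1839-5p, −3.89 for miR-320-5p, −0.90 for miR-1291 and −0.57 for miR-1983. In E518K against KO they were 1.62 for miR-1224-5p, 0.85 for miR-1839-3p, 1.84 for miR-702-3p, 0.41 for miR-320-3p, 2.02 for miR-484, 1.44 for miR-702-5p, 0.72 for miR-1839-5p, 0.60 for miR-320-5p, 0.28 for miR-877-5p, 0.64 for miR-1291 and 1.38 for miR-1983. The median ratio was −2.50 for other miRNAs and 0.237 for the list, and 455 miRNAs were lower and 7 higher in both E518K and KO.

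Untreated E518K against KO had 196 calls with miRNAs that count the same reads merged and 223 with counts divided by 2. With an estimated correlation camera called 0 lists in E518K against wild type, 0 in KO against wild type and 0 in E518K against KO, with 0, 1 and 1 at an unadjusted p under 0.05. Fry called 12 in E518K against wild type, 12 in KO against wild type and 13 in E518K against KO. The median ratio of the DGCR8-independent list was 2.48 with a pseudocount of 0.5 and 1.65 with a pseudocount of 10.

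Leaving out 1 library at a time gave 360 to 418 calls in E518K against wild type, 556 to 615 in KO against wild type, 443 to 478 in E518K against KO, 379 to 401 in untreated wild type against KO and 64 (without KO library 2) to 141 (without KO library 1) in untreated E518K against KO. Called lists ranged from 4 to 5, 7 to 8 and 6 (without KO library 2) to 10 in the first 3. The median ratio ranged from −0.324 to 0.394 (without wild-type clone 16) for other miRNAs and from 2.18 (without wild-type clone 12) to 3.10 (without wild-type clone 16) for the list. In E518K against wild type, miR-320-5p ranged from −3.84 (without E518K clone 13) to 0.11, miR-466c-5p from −0.18 to 0.47 and miR-541-5p from −0.44 to 0.36, each highest without wild-type clone 16.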

Other observations

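Tests of 5 explanations were chosen after the result was seen: those of let-7 against 1 scaling factor and against fibroblast RNA, that of the KO scaling, that of the pRPM totals and that of miRNAs lower in KO. miR-1981, a mirtron whose hairpin fills an intron of Marc2, stood out among miRNAs outside the DGCR8-independent list. miR-1981-5p was at 4165 ± 317 CPM in induced E518K (SD, n = 3) against 328 ± 92.3 in induced wild type, and stayed higher in E518K under every scaling tried. As CPM of all miRNA counts it was 3829 (95% exact binomial interval 3687 to 3975) in wild-type clone 10 without doxycycline and 253 (230.0 to 278) with it. In E518K clone 8 it was 178449 (176384 to 180519) without and 3574 (3452 to 3699.9) with doxycycline, 49.9-fold higher without. Among hairpins of miRNAs higher in E518K with TMM scaling, 58 of 158 had an end within 5 bases of an annotated intron end, against 36 of 326 of the other tested hairpins (Fisher's exact test, odds ratio 4.67, Benjamini-Hochberg p = 2.6e-10 over 7 tests).

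Higher in KO than in wild type were miRNAs of 175 hairpins, of which 87 had an end within 5 bases of an annotated intron end, against 7 of 309 others (Fisher's exact test, odds ratio 42.7, 95% interval 18.7 to 112). Without the DGCR8-independent list the odds ratio was 43.7, and 11 of 167 against 0 of 309 filled a whole intron (13 of 175 with the list). The low-count filter kept a miRNA that reached its CPM limit in a single library, which took the fewest counts in KO. Rare miRNAs could thus enter because they were high there, such as miR-7677-3p (4, 6 and 2 counts in KO, 0 in induced wild type). This can raise these odds ratios, and that for E518K rests on the same filter. With the DGCR8-independent list as scaling 26 of the 219 miRNAs stayed higher in KO, and 15 with pRPM totals as shares. Scaling alone is argued against only for miRNAs that stayed higher. For the rest of the 219 it stays open. Fragments of exons stay open as a further source: 57 of 175 lay in an annotated exon against 55 of 309 (odds ratio 2.23), and without those at an intron end 39 of 88 against 55 of 309 (Fisher's exact test, odds ratio 3.68, Benjamini-Hochberg p = 1.5e-06 over 7 tests). A candidate explanation is that splicing, which needs no DGCR8, made part of these hairpins, and that fragments of exons may account for part of those away from intron ends.

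Let-7 was higher in E518K than in wild type with TMM scaling, although the cells were kept as stem cells. The let-7 median lay 2.35 above that of the other miRNAs, which argues against 1 factor for all miRNAs as the whole cause. Its SE of 0.488 takes the members as independent. With an estimated correlation of 0.651 camera did not call let-7 (adjusted p = 0.63). Fibroblast and mesenchymal markers had a median of −0.125 (SE 0.364, likewise), which changed sign with total counts. They cannot decide on RNA of such cells. Of 23 markers 8 fell and 8 rose in KO, so lower processing could hide a rise. Without wild-type clone 10, 12 or 16 the let-7 median was 1.76, 2.58 and 2.96, the lowest 1.76, so no single wild-type clone made it. With the DGCR8-independent list as scaling the let-7 median was −0.59, so a larger loss of other miRNAs may give the same picture. Differences between the genotypes and between clones of the 2 genotypes stay open and were not tested.

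Across miRNAs the E518K change resembled the difference made by leaving out doxycycline in wild type, but not in the share of the miR-290-295 cluster. Before merging miRNAs that count the same reads, this share was 29.3% in induced E518K against 55.4% in induced wild type. In wild-type clone 10 it was 58.6% without and 57.3% with doxycycline. Across 213 miRNAs with a mean count of at least 200, E518K against wild-type clones 12 and 16 correlated with untreated against induced clone 10, with no library shared (Pearson's r = 0.759, 95% interval 0.704 to 0.806, Spearman's rho = 0.761, slope 1.02), across miRNAs, which are not independent replicates. With libraries thinned to 1050299 counts r was 0.756. Thinning hardly alters the scaled values of miRNAs with so many counts, so it cannot decide on the total of miRNA counts as the cause. A correlation of 0.672 (0.598 to 0.734) across the 178 miRNAs called lower in KO argues against miRNAs that do not need DGCR8 as the whole cause. Leaving out the DGCR8-independent list alone (r = 0.741) removed 6 of 213 miRNAs, too few to decide on that list. This is consistent with lower DGCR8 activity in E518K, a hypothesis found and tested on the same data and with 1 untreated library; E518K protein that is made at a lower level stays open.

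With the group totals of the pRPM values read as shares of a pool of reads, the summed DGCR8-independent list varied 1.85-fold over the 5 groups, against 17.3-fold with the totals as given and 117-fold as a share of the counts. Of 120 ways to assign the 5 totals to the groups 3 were as narrow (exact permutation p = 0.025, smallest possible 0.0083), which is consistent with totals that record the miRNA share of a larger pool.

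Across 153 hairpins the E518K change had Spearman correlations of 0.0076 with GC content, 0.087 with length, 0.093 with folding energy per base and −0.047 with UGU in the loop (permutation p adjusted over 4 features 0.93, 0.58, 0.58 and 0.75). None of the 4 features passed, and for each of them an effect and its absence cannot be told apart at this number of hairpins. The log2 changes of the 5p and 3p arms correlated across 33 hairpins (Pearson's r = 0.826, 95% interval 0.674 to 0.911, Spearman's rho = 0.758), of which 2 count the same reads as another. Without these 2 Pearson's r was 0.888 (0.778 to 0.945) over 31 hairpins, with 14 lower and 10 higher in both arms and 7 that differed in sign. Of these 7, Mir136 had the widest gap, with 3.89 for the 5p arm and −1.09 for the 3p arm.

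Each of the 3 comparisons of induced groups has 10 splits of its 6 libraries, too few for a share under 0.05. The real split called 464 miRNAs for E518K against wild type, 645 for KO against wild type and 497 for E518K against KO, and 1 split, the real one, reached each count. The highest count of another split was 0 in all 3, with 22, 13 and 28 at an unadjusted p under 0.05 by edgeR, where the real ones had 486, 647 and 517. Every other split mixes both real groups within each part, so their difference enters the spread within parts. Hardly any call was possible there, and these counts give no expectation for chance.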
